A study of Mus musculus with 12 samples.

How the data were processed

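Splenic dendritic cells of WT (floxed Xbp1 and Ire1) and KO (Xbp1 and Ire1 deleted in dendritic cells) C57BL6 mice were measured by 10x CITE-seq; the labels name no Cre driver. Each of 4 captures (genotype by pulp) gave an mRNA, an antibody-tag and a hashtag library, so the labels list 12 samples, and 3 hashtags per capture define the hashed replicates. The deposited values are raw UMI counts in 1 filtered matrix per capture, with 55385 genes, 190 antibody tags and 24 hashtags, of which 6 were used. The labels state 160 antibodies and 9 isotype controls, while the matrices hold 190 tags, 9 of them isotype controls, and all 190 were tested. Per the submitters' processing notes, the authors made the deposited counts with Cell Ranger and STAR on mm10 and used Seurat 3.1.4 in later steps; the Cell Ranger version is not stated.

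Hashtags were assigned per capture by a 2-component Gaussian mixture on the log counts of each tag, keeping barcodes with exactly 1 positive tag. Barcodes with several tags made up 6.96% in WT white pulp, 8.45% in WT red pulp, 13.97% in KO white pulp and 7.98% in KO red pulp, and 1.07%, 0.78%, 0.34% and 0.65% had none. Hashtags of the other genotype took 0.0661%, 0.0648%, 0.1073% and 0.0788% of hashtag UMIs. Cells needed at least 500 genes and at most 10% mitochondrial UMIs. Counts were scaled to 10000 per cell and logged, and 2000 variable genes (without Xbp1 and Ern1), 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 31 clusters over all captures with no batch integration (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, scipy 1.17.1). Clusters were named from fixed marker lists, and 4.29% of WT white pulp, 7.09% of WT red pulp, 4.05% of KO white pulp and 5.62% of KO red pulp cells stayed unnamed and were left out.

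Raw counts were summed per class and hashed replicate, keeping sums of at least 10 cells, since cells of 1 replicate are not independent. Sums of immature cDC1 held 2701113 to 25095262 UMIs and sums of mature cDC1 385773 to 5780138, which among cDC1 limits the precision most in mature cells of KO red pulp. Genes were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, limma 3.58.1; TMM, filterByExpr, 1 mean per genotype and pulp, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; the SE is the absolute log2 fold change over the square root of F. Differences of effects between pulps or stages were interaction contrasts, with the replicate as a block between stages. Cell shares were compared by an exact two-sided permutation test and by edgeR on cells per stage, and antibody tags by edgeR with TMM over the panel. For Ccr7, Mki67 and Top2a, cells were also thinned to 4000 UMIs, which left out 232, 534, 361 and 458 cDC1 of WT white, WT red, KO white and KO red pulp. Free RNA was not removed from the counts.

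The 28 gene lists (pathways, RNA handling, markers of other cell types) were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation beside it. At the preset correlation, other splits of the cDC1 samples gave as many lists as KO against WT. The number of lists called therefore does not exclude chance. The gene lists, the comparisons, most alternatives and the rule for named genes were chosen before the data were examined; the T and NK cell comparisons were added later. The rule names, in immature and mature cDC1, Xbp1 and Ern1, the 8 genes each way with the largest mean change among those past 0.05 in both pulps with a mean of at least 30 CPM (without ribosomal protein, mitochondrial and unnamed genes), and up to 4 members per list with the smallest p; other comparisons name up to 5 genes each way. Further list members, lane-wide transcripts and genes beside Itgax were named after their values were seen.

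Replicate numbers were checked for pairing by correlating replicates, centred within their group, over 3760 genes. In immature cDC1 the white and red pulp replicates of 1 number correlated at 0.494 to 0.579 in WT and 0.438 to 0.541 in KO, and those of other numbers at -0.388 to -0.097 in KO and -0.311 to -0.208 in WT, so the numbers paired the pulps there. In mature cDC1, over 3473 genes, those of 1 number correlated at 0.095 to 0.261 in WT (other numbers -0.208 to 0.06) and 0.011 to 0.065 in KO (-0.107 to 0.054). All 6 WT and 4 of 6 KO replicates were closest to their own number, and the pairing was not used in the reported fits between pulps. WT and KO numbers did not pair.

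The method was tested on simulated data with the real levels, spread and depths and 200 changed genes. A fold of 2 was recovered for 73.8% of genes in white and 84.1% in red pulp immature cDC1, and for 91.0% and 57.1% in mature cDC1, with 6.45%, 6.08%, 10.7% and 3.45% false calls. Alternatives were DESeq2 1.42.0, RLE size factors, no gene filter, other hashtag and cell filters, Scrublet (score over 0.2), Leiden resolutions 0.5 and 2, thinning, sums per lane (2 lanes per genotype, pulp as a covariate), a replicate block and each replicate left out. Figures were drawn with matplotlib 3.10.9.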

Results

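Conventional type 1 dendritic cells (cDC1), which take up dying cells and present their antigens to CD8 T cells, were profiled from mouse spleen with RNA and surface antibody tags read in the same cells (CITE-seq). Per the labels, WT mice carried floxed Xbp1 and Ire1 (Ern1) alleles and KO mice lacked both in dendritic cells. Ire1 is the sensor of endoplasmic reticulum (ER) stress that splices Xbp1 mRNA into the form that codes for an active transcription factor. Cells of white pulp, the lymphoid part of the spleen, and of red pulp, its blood-filtering part, were kept apart. Each genotype and pulp was 1 capture with 3 hashed replicates, so there were 4 captures and 12 hashed replicates. Genotype, and pulp within a genotype, therefore changed together with the capture lane. The p-values measure only the spread between hashed samples of a lane, which may be technical. The question given for the series was how homeostatic maturation of cDC1s lacking Xbp1 and Ire1 compared with that of WT cDC1s.

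The 4 captures held 82854409 gene UMIs in WT white pulp, 101282769 in WT red pulp, 98038960 in KO white pulp and 111551283 in KO red pulp. Median gene UMIs per barcode were 7389, 8020, 6260 and 9477 in the same order. Antibody UMIs totalled 6338918, 6634136, 7510510 and 8296947. After hashtag assignment and filtering, 8072, 10314, 10823 and 10428 cells remained. The 3 WT white pulp replicates held 3011, 1782 and 3279 cells, with 29561155, 11811897 and 30211882 gene UMIs. In WT red pulp they held 3597, 3405 and 3312 cells, with 30641932, 27365485 and 29142507 gene UMIs. In KO white pulp they held 3936, 3102 and 3785 cells, with 31174019, 21959095 and 29463266 gene UMIs. In KO red pulp they held 2978, 3698 and 3752 cells, with 27166589, 35185402 and 34107945 gene UMIs.

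Cells were sorted as 65% cDC1, 10% cDC2, 15% pre-DC and 10% live cells, per the labels. Shares of all cells follow this gate, so only shares within cDC1 were compared. Immature cDC1 numbered 1584 in WT white pulp, 5933 in WT red pulp, 3443 in KO white pulp and 6507 in KO red pulp. Mature cDC1, marked by Ccr7, the receptor that guides dendritic cells to T cell zones, numbered 1283, 304, 882 and 170. Cycling cDC1 numbered 761, 853, 1142 and 843. T cells made up 18.7% of WT and 13.3% of KO white pulp cells, and 0.75% and 0.58% of red pulp cells.

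Loss of the targeted genes could not be checked with these reads. The tags lie at the 3′ end of each transcript and need not fall in the deleted part, so they check nothing about the deletion. In immature cDC1, Xbp1 changed by 0.16 ± 0.09 (log2 fold change ± SE of the edgeR fit, KO over WT, n = 3 per group throughout) in white pulp (adjusted p = 0.28). It rose by 0.64 ± 0.08 in red pulp (adjusted p = 7.2e-06). In mature cDC1 it rose by 0.74 ± 0.20 in white pulp (adjusted p = 0.0061) and 0.96 ± 0.27 in red pulp (adjusted p = 0.028). In pre-DC, the precursors of conventional dendritic cells, Xbp1 fell by 1.08 ± 0.12 in white pulp (adjusted p = 3.0e-06) and by 0.97 ± 0.13 in red pulp (adjusted p = 3.6e-05). Ern1 rose in immature cDC1 of red pulp by 0.37 ± 0.11 (adjusted p = 0.016). Its values of 0.40 ± 0.15 in immature cDC1 of white pulp (adjusted p = 0.092), 0.54 ± 0.28 in mature cDC1 of white pulp (adjusted p = 0.15) and 0.59 ± 0.48 in mature cDC1 of red pulp (adjusted p = 0.57) did not pass.

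The mature share of cDC1 was lower in KO than in WT spleens, in both pulps. In white pulp, mature cells made up 34.4% ± 3.27 of WT cDC1 (SD, n = 3, range 31.3 to 37.8). In KO they made up 15.8% ± 1.96 (SD, n = 3, range 13.6 to 17.5), a difference of -18.6 percentage points. In red pulp they made up 4.28% ± 0.745 of WT and 2.24% ± 0.241 of KO cDC1 (SD, n = 3 each), a difference of -2.04 points. The WT and KO replicates did not overlap in either pulp. The exact two-sided permutation test gave p = 0.1 for both, the smallest p that 3 against 3 allows. An edgeR test on cells per stage gave a log2 fold change of -1.13 ± 0.12 in white pulp (adjusted p = 2.5e-06) and -0.92 ± 0.16 in red pulp (adjusted p = 0.0050). With every cell thinned to 4000 UMIs, a Ccr7 UMI was found in 35.8% of WT and 16.3% of KO cDC1 of white pulp, and in 4.73% and 2.22% of red pulp. Unthinned, the shares were 45.6% and 22.7% in white pulp and 6.28% and 3.23% in red pulp. In pre-DC, taken as background, a Ccr7 UMI was found after thinning in 6.07% of WT and 3.99% of KO cells of white pulp (median depths 7534 and 5786 UMIs). In red pulp the background shares were 0.982% and 0.610% (5337 and 5361 UMIs). Clustering again without the genes called between genotypes in cDC1 gave a red pulp difference of -1.24 points, which was over 1.5 times smaller.

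**Figure D1:**
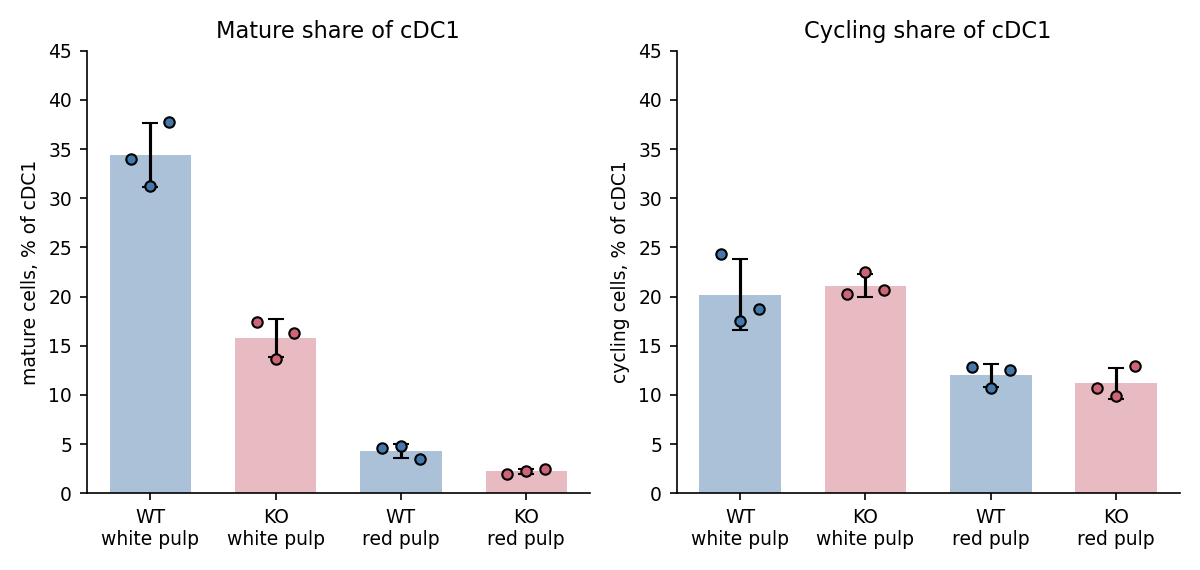
Mature (left) and cycling (right) cells as a percentage of cDC1 in WT and KO white and red pulp. Points are hashed replicates, bars their mean and error bars 1 SD (n = 3); mature cells averaged 34.4% of WT and 15.8% of KO cDC1 in white pulp.

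Cycling cells made up 20.2% ± 3.64 of WT and 21.1% ± 1.21 of KO cDC1 in white pulp (SD, n = 3 each, exact permutation p = 0.7). In red pulp they made up 12.01% ± 1.17 and 11.2% ± 1.55 (exact permutation p = 0.7). The differences of 0.917 and -0.838 points were smaller than the larger SD of each pair. Without WT replicate 1 the white pulp difference was 2.99 points (exact permutation p = 0.1), and without WT replicate 2 it was -0.428. The edgeR tests on cells per stage gave adjusted p = 0.83 and 0.44. After thinning, a UMI of Mki67 or Top2a, genes of dividing cells, was found in 17.8% of WT and 20.2% of KO cDC1 of white pulp. The replicates did not overlap there (exact permutation p = 0.1, n = 3 each, the smallest possible), with a difference of 2.37 points. In pre-DC of white pulp such a UMI was found in 3.64% of WT and 4.84% of KO cells, so part of that difference was also seen there. In red pulp the difference by this measure was 0.605 points, in the other direction from that of the clusters.

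Immature cDC1 of KO spleens carried far more transcripts of genes on the PERK-ATF4-CHOP list. That arm of the stress response adjusts amino acid supply and translation and can lead to cell death. Only transcripts of the list were read, so activity of PERK itself was not measured. Asns, which makes asparagine, rose by 4.04 ± 0.26 in white pulp (adjusted p = 4.1e-09) and 5.68 ± 0.22 in red pulp (adjusted p = 2.7e-12). Ddit3, which codes for the transcription factor CHOP, rose by 2.70 ± 0.12 (adjusted p = 5.2e-11) and 3.01 ± 0.10 (adjusted p = 4.5e-13). The transcription factor gene Atf5 rose by 4.07 and 5.05, Phgdh, the first enzyme of serine synthesis, by 2.84 and 4.20, and Cebpb by 2.00 and 2.83. Cox6a2, a subunit of cytochrome c oxidase that is also on the list of plasmacytoid dendritic cell markers, rose from 2.24 to 143 CPM in white pulp (5.93 ± 0.32, adjusted p = 7.1e-10). In red pulp it rose from 0.918 to 125 CPM (7.09 ± 0.29, adjusted p = 4.2e-12). Cox6a2 is not on the PERK-ATF4-CHOP list, and it also rose in pre-DC, cDC2 and NK cells of both pulps. Ifitm6 rose by 2.51 and 2.59, and Cdkn1a, an inhibitor of the cell cycle, by 1.66 and 2.75. The cytokine gene Tnf fell by 1.31 ± 0.19 in white pulp (adjusted p = 6.7e-05) and 1.59 ± 0.15 in red pulp. Apol7c fell by 1.33 and 1.06, Snd1 by 1.26 and 0.87, and Nucb2 by 1.09 and 0.56. Ost4, a subunit of the complex that adds sugars to new proteins, fell by 0.88 and 0.71, and Pianp by 0.84 and 0.74. The inflammatory cytokine gene Il6 rose by 2.05 and 2.42. In all, 1635 of 12544 genes passed in white pulp (826 up, 809 down) and 3299 in red pulp (1633 up, 1666 down). Of these, 626 were up and 603 down in both, against 108 and 107 from independent calls, and 7 in opposite directions. With cells thinned to 1 depth the counts were 927 and 2103. A fit on sums per capture lane, which gives 1 effect over both pulps, called 2821 genes.

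Of 24 PERK-ATF4-CHOP genes tested in immature cDC1, 22 rose and 0 fell in white pulp (22 and 1 adjusted over the list alone; median 1.76; camera adjusted p = 5.7e-27, and adjusted p = 0.037 with an estimated correlation). In red pulp 22 rose and 1 fell (22 and 1 adjusted over the list alone; median 2.09; adjusted p = 1.7e-28, and adjusted p = 0.031 with an estimated correlation). In immature cDC1, genes that the spliced form of XBP1 controls mostly fell. Of 50, 8 rose and 32 fell in white pulp (8 and 33 adjusted over the list alone; median -0.32; adjusted p = 3.3e-11, and adjusted p = 0.34 with an estimated correlation). In red pulp 12 rose and 28 fell (12 and 30 adjusted over the list alone; median -0.25; adjusted p = 0.00024, and adjusted p = 0.44 with an estimated correlation). Those that fell included Sec61b, part of the channel that brings new proteins into the ER, by 0.96 ± 0.04 (adjusted p = 5.0e-11) and 0.99 ± 0.04 (adjusted p = 4.2e-12). Sec24d, part of the coat of vesicles leaving the ER, fell by 1.35 and 1.14, and the co-chaperone Dnajb9 by 1.14 and 1.00. Those that rose included the protein disulfide isomerases Pdia4, by 0.52 and 1.27, and Pdia6, by 0.43 and 0.99. Manf rose by 0.74 and 1.32 and Sel1l, part of the machinery that removes misfolded proteins, by 0.91 and 1.34. Of 13 ATF6-type ER chaperones, 9 rose and 2 fell in white pulp (9 and 3 adjusted over the list alone; adjusted p = 0.00024, and adjusted p = 0.55 with an estimated correlation). In red pulp 11 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 9.8e-13, and adjusted p = 0.24 with an estimated correlation). Among these Hspa5, the main ER chaperone, rose by 1.15 ± 0.07 and 1.71 ± 0.07, Hsp90b1 by 1.06 and 1.57, and Calr by 0.72 and 1.23. The lists share members, so their counts are not independent. Pdia4, Manf, Hyou1, Creld2, Sdf2l1 and Dnajb11 are on both the chaperone and the XBP1s-dependent list. Herpud1 is on both the chaperone and the PERK-ATF4-CHOP list.

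**Figure D2:**
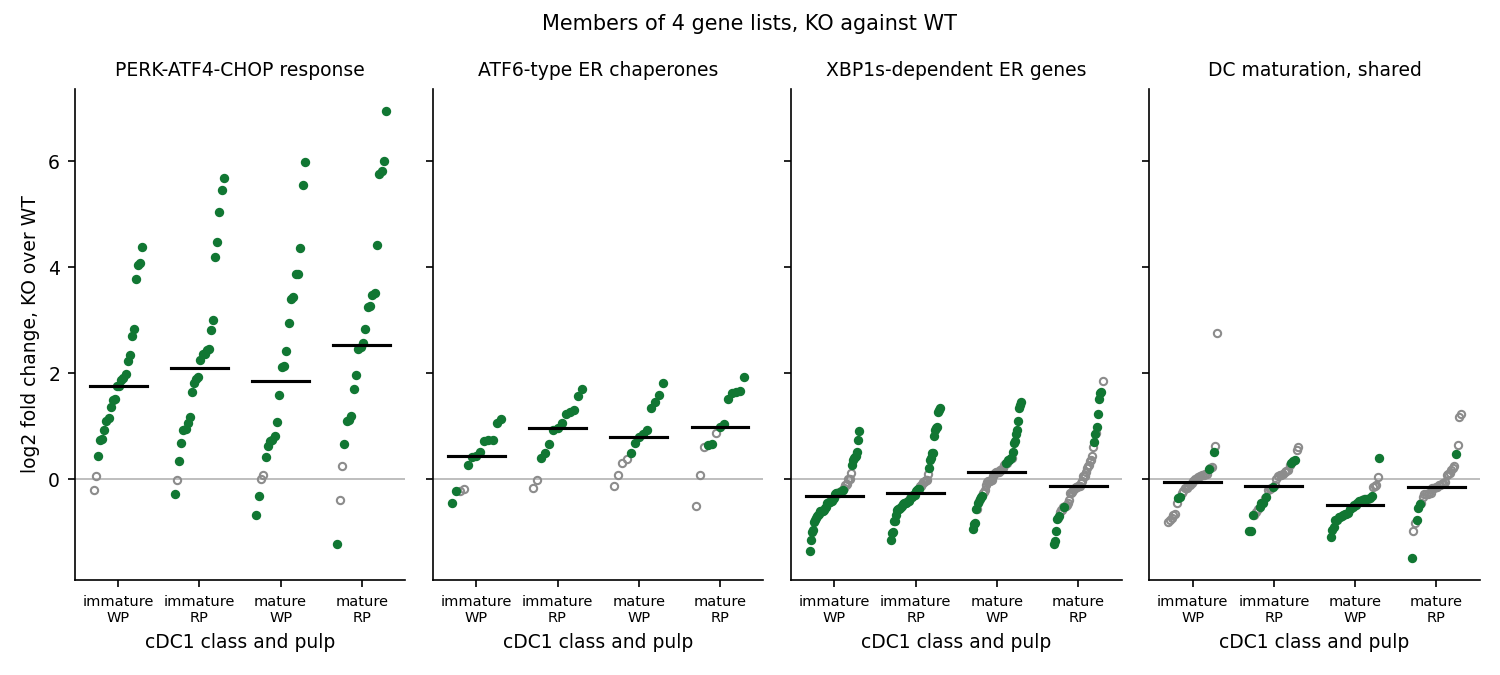
Log2 fold change, KO over WT, of each member of 4 gene lists in immature and mature cDC1 of white pulp (WP) and red pulp (RP). Filled points passed an adjusted p of 0.05, open points did not, and black bars are medians, at 1.76, 2.09, 1.85 and 2.53 for the PERK-ATF4-CHOP list.

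Of 20 cDC1 identity genes, 0 rose and 10 fell in white pulp immature cDC1 (1 and 11 adjusted over the list alone; adjusted p = 0.00098, and adjusted p = 0.34 with an estimated correlation). In red pulp 1 rose and 11 fell (1 and 11 adjusted over the list alone; adjusted p = 0.0070, and adjusted p = 0.40 with an estimated correlation). Itgae, which codes for CD103, fell by 1.56 and 1.32, Cd8a by 0.43 and 0.32, and Xcr1, the receptor for a chemokine made by T and NK cells, by 0.25 and 0.34. In red pulp, 7 of 16 glycolysis genes rose and 0 fell (adjusted p = 0.039, and adjusted p = 0.44 with an estimated correlation), such as Gapdh by 0.29 ± 0.04. There, 1 of 12 genes of MHC class II presentation rose and 7 fell (adjusted p = 0.033, and adjusted p = 0.44 with an estimated correlation), such as H2-Oa by 0.36 ± 0.06. The glycolysis call was lost without WT replicate 2 (adjusted p = 0.11) or KO replicate 2 (0.0522) and after thinning (0.0505). The class II call was lost without KO replicate 1 (0.0665) or 3 (0.0547). Markers of red blood cells also moved. Of 5, 0 rose and 1, Car2, fell in white pulp (0 and 5 adjusted over the list alone; median -4.00; adjusted p = 0.031, and adjusted p = 0.62 with an estimated correlation). This call was lost without KO replicate 3 (0.073) and after thinning (0.14). The other 22 lists in white pulp and 21 in red pulp did not pass, with adjusted p from 0.069 to 0.99 and from 0.060 to 0.98. In red pulp 6 lists passed, against 12 with the replicate block, 10 with no gene filter, and 10 and 11 without WT replicates 1 and 3. Immunoglobulin transcripts, which cDC1 do not make, were lower in KO lanes, with Igkc at -0.85 ± 0.10 and -1.06 ± 0.19. The mitochondrial ribosomal RNA mt-Rnr2, a sign of RNA handling, was at -0.62 ± 0.04 and -0.72 ± 0.04.

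The genotype effect in immature cDC1 differed between pulps for 112 genes by the interaction test (65 higher and 47 lower in white than in red pulp). Rises of ER chaperones were smaller in white pulp. Of 13 ATF6-type chaperones, 0 were higher and 9 lower (0 and 12 adjusted over the list alone; median -0.52; adjusted p = 2.6e-15, and adjusted p = 0.14 with an estimated correlation). Among these were Calr at -0.51 ± 0.06 (adjusted p = 0.00072) and Hspa5 at -0.56 ± 0.09 (adjusted p = 0.0064). Of 50 XBP1s-dependent genes 1 was higher and 9 lower (1 and 14 adjusted over the list alone; adjusted p = 2.0e-08, and adjusted p = 0.32 with an estimated correlation). Of 24 PERK-ATF4-CHOP genes 0 were higher and 4 lower (1 and 11 adjusted over the list alone; adjusted p = 3.4e-06, and adjusted p = 0.32 with an estimated correlation). Phgdh differed by -1.36, Cdkn1a by -1.09, Creld2 by -0.84, Cebpb by -0.83 and Pdia4 by -0.75. Creld2 and Pdia4 are on both the chaperone and the XBP1s-dependent list. Lars2 differed by 0.60, Sec61g by 0.52 and Sod1 by 0.43. Glycolysis genes were lower (0 and 1 of 16; 0 and 6 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.32 with an estimated correlation). Markers of other cells moved alongside. Of 3 NK cell markers 2 were higher, Gzma at 2.82 ± 0.48 and Nkg7 at 2.44 ± 0.54 (adjusted p = 0.0017, and adjusted p = 0.14 with an estimated correlation). T cell markers had a median of 1.13 with 0 of 9 called (2 and 0 adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.32 with an estimated correlation). That call was lost without WT replicate 2 (0.133) or 3 (0.0699) and without KO replicate 1 (0.0875) or 3 (0.0712). The other 21 lists did not pass, with adjusted p from 0.080 to 0.92. With the replicate number as a block the count was 564, and with no gene filter 249. It was 64 and 71 without WT replicates 2 and 3 and 24, 40 and 43 without KO replicates 1, 2 and 3.

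Mature cDC1 of KO spleens also carried more transcripts of genes on the PERK-ATF4-CHOP list. In white pulp many genes that dendritic cells switch on as they mature were lower, though their list did not pass with an estimated correlation (adjusted p = 0.20) and fewer fell within single clusters. Atf5 rose by 3.87 ± 0.20 in white pulp (adjusted p = 5.9e-13) and 5.81 ± 0.38 in red pulp (adjusted p = 4.7e-11), Ddit3 by 2.12 ± 0.13 and 3.24 ± 0.19, and Phgdh by 4.37 and 6.94. Slc7a11, a cystine transporter, rose by 2.15 and 3.27, Sars by 2.42 and 2.83, and Eif4ebp1, a brake on translation, by 3.23 and 3.39. Cox6a2 rose by 5.69 and 5.89, and Ifitm6 by 2.49 and 2.83. Il4i1, an enzyme of amino acid breakdown in mature dendritic cells, fell by 0.95 ± 0.09 (adjusted p = 1.6e-08) and 1.47 ± 0.13 (adjusted p = 1.5e-08). The cytokine gene Il1b fell by 0.94 and 1.46, H2-M2 by 1.89 and 6.25, and Gbp4 by 1.79 and 1.59. Apol7c fell by 1.24 and 1.58, Specc1 by 1.17 and 1.14, Mical3 by 1.11 and 1.06, and Idh1 by 0.99 and 1.30. In all, 2582 of 7467 genes passed in white pulp (1153 up, 1429 down) and 515 in red pulp (272 up, 243 down). Of these, 197 were up and 137 down in both, against 42.0 and 46.5 from independent calls, and 25 in opposite directions. Mature cDC1 formed 2 clusters. Cluster 7 held 79.0% ± 5.19 of WT and 60.4% ± 4.84 of KO mature cells in white pulp (SD, n = 3 each). Within cluster 7 alone 1014 genes passed and within cluster 13 alone 848. Thinning gave 1533 and 287 in the 2 pulps, and the red pulp count was 329 without KO replicate 2. A fit on sums per lane, with 1 effect over both pulps, called 446 genes.

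Of 22 PERK-ATF4-CHOP genes in mature cDC1, 18 rose and 2 fell in white pulp (18 and 2 adjusted over the list alone; median 1.85; adjusted p = 4.7e-13, and adjusted p = 0.0064 with an estimated correlation). In red pulp 19 rose and 1 fell (20 and 2 adjusted over the list alone; median 2.53; adjusted p = 1.5e-23, and adjusted p = 0.00078 with an estimated correlation). ATF6-type chaperones rose in both, 9 and 0 of 13 in white pulp (9 and 0 adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.15 with an estimated correlation). The red pulp counts were 9 and 0 (10 and 0 adjusted over the list alone; adjusted p = 3.2e-11, and adjusted p = 0.070 with an estimated correlation), with Hspa5 at 1.58 ± 0.10 and 1.66 ± 0.10. Of 32 genes shared by dendritic cell maturation programs, 1 rose and 24 fell in white pulp (1 and 25 adjusted over the list alone; median -0.48; adjusted p = 6.5e-07, and adjusted p = 0.20 with an estimated correlation). The death receptor gene Fas fell by 1.08 ± 0.12 (adjusted p = 2.1e-07), Traf1 by 0.77, Ccr7 by 0.65 (adjusted p = 2.8e-05) and Cd274, which codes for PD-L1, by 0.70. Within cluster 13 alone 0 of 29 rose and 10 fell, and within cluster 7 alone 2 of 34 rose and 8 fell. Cholesterol synthesis genes fell in white pulp, 0 and 10 of 19 (0 and 11 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.25 with an estimated correlation). Idi1 fell by 0.90. That call was lost without KO replicate 3 (adjusted p = 0.056), after thinning (0.10) and within cluster 13 alone (0.10, in the other direction). Transcripts that mark the lane moved with these lists in white pulp, with Igkc at -2.57 ± 0.55 (adjusted p = 0.00077) and mt-Rnr2 at -0.62 ± 0.08 (adjusted p = 1.4e-06). Igkc there was at 208 CPM in WT (SD 265, n = 3) and 37.8 in KO (SD 12.3). The WT SD exceeded the mean, so the size of that fall is uncertain. In red pulp mt-Rnr2 was at -0.54 ± 0.08 (adjusted p = 6.1e-05) and Igkc at 0.06 ± 2.72.

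MHC class II presentation genes rose in mature cDC1 of white pulp, 9 and 0 of 12 (10 and 0 adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.17 with an estimated correlation). H2-DMa rose by 0.88 ± 0.09 and H2-Ab1 by 0.63 ± 0.08. Oxidative phosphorylation genes rose, 10 and 0 of 21 (adjusted p = 0.00013, and adjusted p = 0.20 with an estimated correlation), such as Uqcrq by 0.88. Glycolysis genes rose as well, 7 and 0 of 13 (9 and 0 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.15 with an estimated correlation), such as Ldha by 0.76. Inflammatory NF-kB genes fell, 1 and 7 of 15 (1 and 8 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.20 with an estimated correlation). Birc3 was at -0.74 and Il6 at 1.88. Within cluster 13 alone the class II (adjusted p = 0.33) and glycolysis (0.13) calls were lost. The NF-kB call was lost without KO replicate 3 (0.061). In red pulp, cDC1 identity genes fell, 1 and 5 of 20 (1 and 7 adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.52 with an estimated correlation), with Cd8a at -0.85 ± 0.11. The call was lost without WT replicate 1 (0.0924) or 2 (0.0541), without KO replicate 1 (0.118) or 3 (0.102), and after thinning (0.164). Red blood cell markers fell with them, 0 and 2 of 3, with Hba-a1 at -4.46 ± 1.21 (adjusted p = 0.024 for the list, and adjusted p = 0.26 with an estimated correlation), a call lost without WT replicate 3 (0.059). Without WT replicate 1, after thinning and within cluster 13 alone, too few of these markers were left to test the list. The other 15 lists in white pulp and 19 in red pulp did not pass, with adjusted p from 0.071 to 0.98 and from 0.096 to 1.00. Among them were the XBP1s-dependent ER genes, which did not mostly fall in mature cDC1. Of 49, 13 rose and 8 fell in white pulp (median 0.13), and 7 rose and 6 fell in red pulp (median -0.13).

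In mature cDC1, the genotype effect differed between pulps for 313 genes (197 higher and 116 lower in white pulp). Class II presentation genes were higher, 8 and 0 of 12 (10 and 0 adjusted over the list alone; median 0.69; adjusted p = 9.4e-08, and adjusted p = 0.13 with an estimated correlation), as H2-Ab1 at 0.82 ± 0.11 (adjusted p = 0.00028). PERK-ATF4-CHOP genes were lower, 0 and 8 of 22 (1 and 10 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.062 with an estimated correlation), as Ddit3 at -1.12 ± 0.25 (adjusted p = 0.010). Maturation genes were lower, 1 and 4 of 32 (2 and 6 adjusted over the list alone; adjusted p = 0.0056, and adjusted p = 0.60 with an estimated correlation), as Fas at -1.72 ± 0.29. That call was lost without KO replicate 3 (adjusted p = 0.24). Oxidative phosphorylation genes were higher, 3 and 0 of 21 (7 and 0 adjusted over the list alone; adjusted p = 0.00094, and adjusted p = 0.35 with an estimated correlation). So were cDC1 identity genes, 5 and 0 of 20 (9 and 2 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.35 with an estimated correlation). Il15ra, which presents the cytokine IL-15, differed by -2.02, Gbp8 by -1.97, Cebpb by -1.89 and Gtpbp2 by -1.53. H2-M2 differed by 4.36, Ms4a1 by 1.41, Lsm6 by 1.28, Wdr83os by 1.26 and the kinase gene Syk by 1.20. The other 18 lists did not pass, with adjusted p from 0.064 to 0.99. The count was 205 without WT replicate 1 and 119, 143 and 162 without KO replicates 1, 2 and 3.

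The genotype effect also differed between mature and immature cDC1, for 1845 genes in white pulp (1100 higher and 745 lower in mature cells) and 90 in red pulp (32 and 58). With RLE size factors the white pulp genes split almost evenly, 924 higher and 901 lower. In white pulp, cluster 7 held 79.0% of WT and 60.4% of KO mature cells. The contrast there therefore mixes 2 mature clusters in different proportions, and it was not run within single clusters. In white pulp Phgdh differed by 1.61, Krtcap2 by 1.53, Eif4ebp1 by 1.33, Denr by 1.33 and Parvg by 1.32. Gbp8 differed by -2.48, Cdkn1a by -1.57, Gbp4 by -1.56 and Rbpms by -1.44. In red pulp Phgdh differed by 2.78, Ccl22, a chemokine that draws T cells, by 1.42, Eif4ebp1 and Krtcap2 by 1.07 each and Gclm by 0.97. Cdkn1a differed by -1.81, Ccnd2 by -1.57 and Ms4a1 by -1.15. The white pulp count was 1202 without WT replicate 3, and the red pulp count was 58 without WT replicate 1 and 26 with no replicate block.

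Averaged over their cells, immature cDC1 of white pulp had more transcripts of interferon-stimulated genes than those of red pulp, in both genotypes. Within a genotype each pulp was 1 capture lane, so effects of pulp and lane cannot be told apart. Many maturation genes were higher as well, though in WT their list did not pass with an estimated correlation (adjusted p = 0.11). After thinning, a Ccr7 UMI was found in 7.73% of white and 1.82% of red pulp WT immature cDC1 (4.90% and 0.887% in KO). In pre-DC, taken as background, it was found in 6.07% and 0.982% (3.99% and 0.610% in KO). Free RNA may therefore contribute to the Ccr7 difference, and its part in the list was not tested. In WT immature cDC1, Cxcl10, a chemokine that interferon induces, was higher in white pulp by 2.23 ± 0.22 (adjusted p = 2.8e-06). Serpina3g was higher by 1.92, Vim by 1.62, Cxcl9 by 1.46 and Cd40, a receptor for T cell help, by 1.41. Apoe was at -1.38 ± 0.08 (adjusted p = 6.7e-09), Ifitm6 at -1.04, Hfe at -0.82 and Pianp at -0.80. In KO immature cDC1, Cxcl10 was at 1.91, Serpina3g at 1.68, Vim at 1.62, Cxcl9 at 1.53 and Mndal at 1.31. Apoe was at -1.50, the heme-degrading enzyme gene Hmox1 at -1.45, Ifitm6 at -1.12, the metal transporter gene Slc11a1 at -1.05 and Fndc5 at -0.92. Cluster 12, whose top genes include Cxcl9, Cxcl10 and Serpina3g, held 209 of 1584 WT immature cDC1 in white and 150 of 5933 in red pulp. In KO it held 497 of 3443 and 184 of 6507. The pulps were not compared without it, so its share cannot be told from a rise in all cells. The counts were 1335 genes in WT (683 up, 652 down) and 1248 in KO (623 up, 625 down). Of these, 315 were up and 303 down in both, against 33.9 and 32.5 from independent calls and 13 opposite. The replicate numbers paired the pulps of immature cDC1, and with them as a block 2262 and 2471 genes passed. The WT count was 824 and 595 without WT replicates 2 and 3, and the KO count 535, 788 and 634 without KO replicates 1, 2 and 3.

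Of 34 interferon-stimulated genes, 28 were higher and 0 lower in white pulp in WT immature cDC1 (28 and 0 adjusted over the list alone; adjusted p = 8.2e-22, and adjusted p = 0.029 with an estimated correlation). The KO counts were 28 and 0 (31 and 0 adjusted over the list alone; adjusted p = 1.4e-26, and adjusted p = 0.0065 with an estimated correlation). Of 30 maturation genes 14 were higher and 1 lower in WT (16 and 3 adjusted over the list alone; adjusted p = 7.0e-08, and adjusted p = 0.11 with an estimated correlation). In KO, 17 were higher and 1 lower (18 and 1 adjusted over the list alone; adjusted p = 3.2e-11, and adjusted p = 0.050 with an estimated correlation). Identity genes were lower, 2 and 9 of 20 in WT (2 and 13 adjusted over the list alone; adjusted p = 0.00014, and adjusted p = 0.11 with an estimated correlation). For KO cells the counts were 1 and 11 (1 and 13 adjusted over the list alone; adjusted p = 3.8e-06, and adjusted p = 0.047 with an estimated correlation). Cell cycle genes were higher, 6 and 1 in WT (11 and 1 adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.11 with an estimated correlation). Among KO cells 7 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.051 with an estimated correlation). ATF6-type chaperones were higher in white pulp in WT, 10 and 0 of 13 (12 and 0 adjusted over the list alone; adjusted p = 7.2e-08, and adjusted p = 0.14 with an estimated correlation). They were lower in KO, 0 and 4 (0 and 6 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.33 with an estimated correlation). Markers of T cells moved with these lists, with medians of 2.92 in WT and 4.12 in KO (adjusted p = 1.2e-07 and 7.2e-13, and adjusted p = 0.044 and 0.0065 with an estimated correlation). So did neutrophil markers, with medians of 2.99 and 2.96 (adjusted p = 4.4e-05 and 5.2e-07, and adjusted p = 0.029 and 0.0065 with an estimated correlation). In all, 14 of 27 lists passed in WT and 15 in KO, of which 3 and 7 did so with an estimated correlation.

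In mature cDC1 more genes but fewer lists passed between the pulps than in immature cDC1. The genes and lists tested and the depths differ between the stages, and this difference was not tested. Of 19 cholesterol synthesis genes 18 were higher in white pulp in WT (18 and 0 adjusted over the list alone; median 1.65; adjusted p = 1.5e-08, and adjusted p = 0.087 with an estimated correlation). In KO, 13 were higher (18 and 0 adjusted over the list alone; median 1.47; adjusted p = 4.2e-11, and adjusted p = 0.036 with an estimated correlation). Of 32 maturation genes 27 were higher and 2 lower in WT (28 and 2 adjusted over the list alone; adjusted p = 1.3e-10, and adjusted p = 0.15 with an estimated correlation). For KO the counts were 21 and 2 (23 and 3 adjusted over the list alone; adjusted p = 2.2e-10, and adjusted p = 0.17 with an estimated correlation). Identity genes were lower, 4 and 16 of 20 in WT (adjusted p = 2.8e-05, and adjusted p = 0.15 with an estimated correlation) and 3 and 14 in KO (adjusted p = 5.1e-05, and adjusted p = 0.17 with an estimated correlation). The chemokine gene Ccl5 was higher in white pulp by 5.13 ± 0.21 in WT (adjusted p = 9.0e-16) and 4.87 ± 0.22 in KO, Idi1 by 3.58 and 2.61, and Synpo2 by 4.56 and 4.17. Hmox1 was at -2.93 and -4.34. The antibody transcript Igkc was at 5.53 in WT, where its white pulp SD of 265 CPM exceeded the mean of 208 CPM (n = 3). The counts were 3590 genes in WT (1837 up, 1753 down) and 1823 in KO (923 up, 900 down), with 817 up and 713 down in both. Interferon-stimulated genes did not pass as a list in mature cDC1 (adjusted p = 0.28 in WT and 0.099 in KO). In all, 10 of 23 lists passed in WT and 11 in KO, of which 0 and 1 did so with an estimated correlation. The KO count was 1160 and 1122 without KO replicates 1 and 2. The share of cluster 7 among mature WT cells was 79.0% in white and 12.2% in red pulp.

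Fewer genes passed in pre-DC and cDC2, whose sums differ in depth from those of cDC1, and the difference was not tested. In pre-DC 127 of 9374 genes passed in white pulp (73 up, 54 down) and 116 in red pulp (52 up, 64 down). Cox6a2 rose by 4.40 ± 0.23 and 4.84 ± 0.28. Plcb4 rose by 1.93 and 1.83, the chemokine gene Ccl3 by 1.32 and 1.08, and the integrin gene Itgam by 0.97 and 1.30. XBP1s-dependent ER genes fell in pre-DC, 0 and 4 of 50 in white pulp (0 and 16 adjusted over the list alone; adjusted p = 3.2e-10, and adjusted p = 0.00074 with an estimated correlation). The red pulp counts were 0 and 8 (0 and 13 adjusted over the list alone; adjusted p = 5.9e-06, and adjusted p = 0.0051 with an estimated correlation). P4hb fell by 0.65 in white pulp. Transcripts that mark the lane fell with them, with mt-Rnr2 at -0.63 ± 0.05 (adjusted p = 2.7e-09) and -0.48 ± 0.05 (adjusted p = 3.5e-07), and Igkc at -0.72 ± 0.18 in white pulp (adjusted p = 0.039). Without a gene filter the pre-DC counts were 235 and 219. They were 67 and 82 in white pulp without KO replicates 1 and 3, and 64, 58 and 42 in red pulp without WT replicate 3 and KO replicates 1 and 3. In cDC2, 13 of 7658 genes passed in white pulp (8 up, 5 down) and 16 in red pulp (9 up, 7 down). Cox6a2 was at 5.26 ± 0.66 and 6.32 ± 0.67 and Plcb4 at 2.67 and 2.78. The cDC2 counts without a gene filter were 44 and 41, DESeq2 gave 22 in white pulp, and single left-out replicates gave 4 to 23 and 9 to 23. In B cells of white pulp edgeR called 0 of 2411 genes, with 266 at an unadjusted p under 0.05, while DESeq2 called 14. The XBP1s-dependent ER genes had a median of -0.85 there, with 0 of 42 called. The top genes of this class included Igkc, Igha and Jchain, so antibody-secreting plasma cells may be among its cells. Igha was at 84070 CPM in WT (SD 51427) and 5259 CPM in KO (SD 4498, n = 3 each, adjusted p = 0.27). A different share of plasma cells between the lanes was not tested and may contribute to that median. Red pulp held too few B cells to test.

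On the cell surface, the tag for CD207 (langerin), a lectin that binds sugars, fell most. In immature cDC1 it was at -1.95 ± 0.25 in white pulp (adjusted p = 0.00045) and -3.00 ± 0.25 in red pulp (adjusted p = 7.4e-06), and its transcript Cd207 fell by 1.79 and 1.84. In mature cDC1 the tag was at -3.10 and -3.57, and Cd207 fell by 2.29 and 1.26. Counts of the tag per mature cell were 2.00 and 3.04 in WT and 0.251 and 0.357 in KO. They did not stand above the highest isotype control in every replicate of both genotypes, a rule that a tag lost in KO can fail by that loss. Of 190 tags, 13 passed in white pulp immature cDC1 (1 up, 12 down), 29 in red pulp (11 up, 18 down, of which 1 was an isotype control), 27 in white pulp mature cDC1 (8 up, 19 down) and 18 in red pulp (6 up, 12 down). In immature cDC1 the tag for CD8a fell by 0.59 and 0.49 in the 2 pulps. So did that for CD73, an enzyme that makes adenosine, by 0.53 and 0.43, ESAM by 0.56 and 0.40, and IA_IE (MHC class II) by 0.58 and 0.38. CD135 was at -0.55 and -1.03, where its counts did not stand above the isotype controls in every replicate of both genotypes. In mature cDC1, CD102 rose by 0.54 and 0.61 and CD371 by 0.57 and 0.47. CD106, an adhesion molecule, fell by 0.68 and 0.75, CD38 by 0.70 and 0.36 and CD8a by 0.53 and 0.51. IA_IE fell by 0.54 (adjusted p = 7.2e-07) and 0.33 in mature cDC1, while the class II transcript H2-Ab1 rose there in white pulp by 0.63. Many of these calls were lost when tags were scaled by the isotype controls. In immature cDC1 they were lost in red pulp for CD8a (-0.21, adjusted p = 0.24), CD73 (-0.16, 0.52), ESAM (-0.12, 0.62) and IA_IE (-0.10, 0.64). In white pulp they were lost for CD73 (adjusted p = 0.11), ESAM (0.086) and CD135 (0.20). In mature cDC1 they were lost in both pulps for CD106 (adjusted p = 0.083 and 0.42) and CD8a (0.12 and 0.78), and in white pulp for CD102 (0.12). The red pulp values of CD38 and IA_IE in mature cDC1 were 0.023 and 0.046, with the sign turned. Isotype scaling gave 7 and 12 calls in white pulp, and in red pulp 26 up and 5 down in immature and 11 up and 2 down in mature cDC1, so the balance of rises and falls turned. Total panel counts turned it in mature cDC1 of white (25 up, 9 down) and red pulp (14 up, 7 down) and in immature cDC1 of white pulp (5 up, 4 down). Leaving out tags not above the isotype controls turned it in immature cDC1 of red pulp (13 up, 12 down). In mature cDC1 of white pulp it also turned without WT replicate 1 (15 up, 12 down) or 3 (12 up, 9 down) and without KO replicate 1 (11 up, 8 down). Single left-out replicates gave 3 to 26, 5 to 47, 19 to 27 and 9 to 17 calls in the 4 comparisons.

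**Figure D3:**
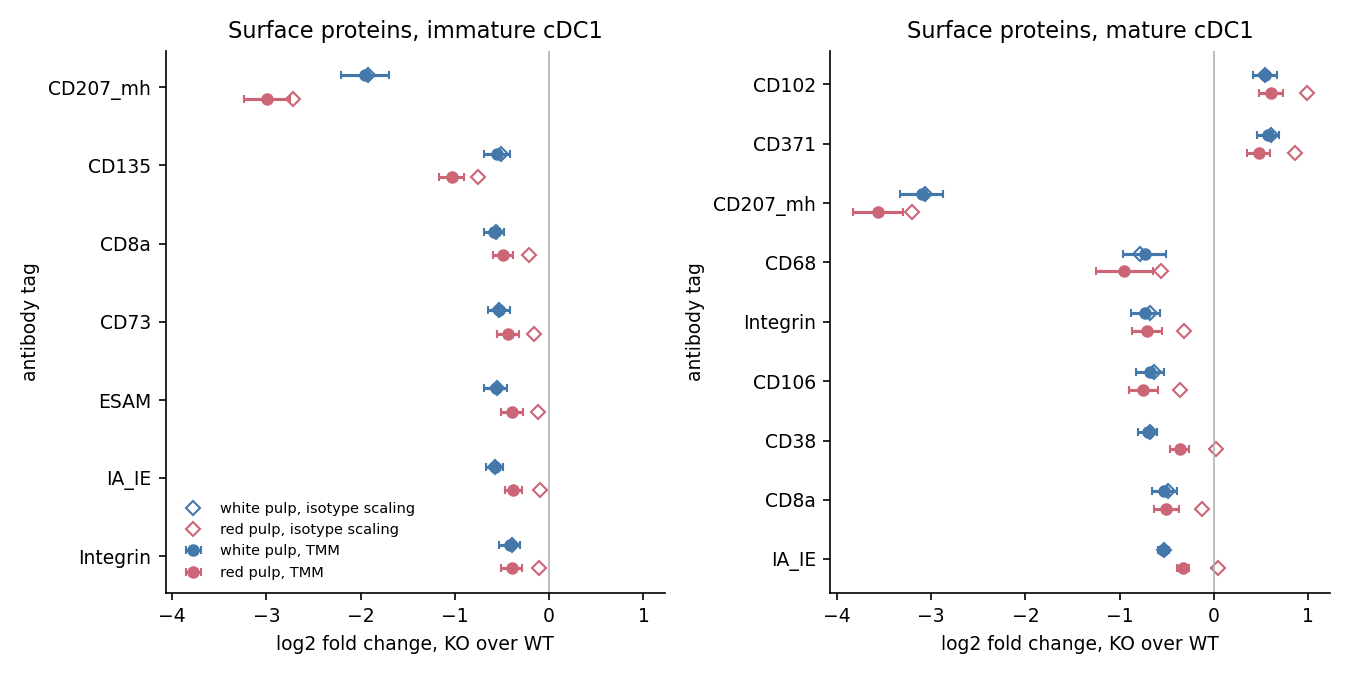
Log2 fold change, KO over WT, of antibody tags called in the same direction in both pulps, in immature (left) and mature (right) cDC1. Filled points with bars are edgeR estimates with TMM scaling ± SE, open diamonds are values scaled by the isotype controls; CD207 was at -1.92 or lower under both scalings.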

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

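The counts over other splits of the samples were chosen as tests only after the results were seen.

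In immature cDC1 the genotype effect differed between pulps for 112 genes by the interaction test. Of 40 draws that moved genotype labels within each pulp separately, the real one included, 5 gave as many genes, with up to 1353, so chance was not excluded by this count. The 4 other draws with as many genes each kept at least 4 more true labels in 1 pulp than in the other. Such draws leave the full genotype effect of 1 pulp, in either direction, in the contrast. The highest count among the 20 draws that kept equal numbers was 0. Those draws mix WT and KO in each group, which shrinks any difference and widens the spread, so this 0 decides nothing. Where labels moved with the replicate in both pulps, 1 of 10 splits gave as many genes, the real one, and the highest other was 0. The other splits also mix WT and KO, and 10 splits are too few for a share under 0.05.

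In mature cDC1 the effect differed between pulps for 313 genes. Here 6 of 40 draws gave as many genes, the real one included, with up to 723, so chance was not excluded by this count either. The 5 other draws also kept at least 4 more true labels in 1 pulp. The highest count among the 11 draws with equal numbers was 0, which decides nothing for the same reason. With labels moved by replicate, 1 of 10 splits gave as many and the highest other was 0. Those splits also mix WT and KO and are too few for a share under 0.05. In white pulp, cluster 7 held 79.0% of WT and 60.4% of KO mature cells, so the averages compared there mix 2 clusters in different proportions.

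Between mature and immature cDC1 the effect differed for 1845 genes in white pulp and 90 in red pulp, both by the interaction test. In white pulp, cluster 7 held 79.0% of WT and 60.4% of KO mature cells, so the mature averages mix 2 clusters in different proportions. In each pulp 1 of 10 splits, the real one, gave as many genes. The highest other gave 2 in white and 17 in red pulp. Other splits mix WT and KO in each group, which shrinks any difference, and are too few for a share under 0.05.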

How the results depend on the processing

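Settings chosen only after the results were seen were the clusters 7, 8, 12 and 13 treated apart, the clustering without called genes, the unthinned shares, and every T and NK cell comparison. Of 397 values of the compared counts and shares under an alternative, 306 stayed within 1.5 times or 1 SD, and 91 did not, 49 of these with 1 replicate left out. Within 1 SD, the uncalled cycling share still changed sign in white pulp without WT replicate 2 and in red pulp without thinning (0.532 points). Of 7946 values of named genes, 7331 kept direction and side of the threshold, 429 lost the call, 105 gained one, 12 turned and 69 moved; of 64 tag values 33 kept, 29 lost the call and 2 turned. The cause was not tested unless given. Among cDC1, depth limits mature cells of red pulp most, where a simulated fold of 1.5 was found for 20.0% of genes.

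After thinning, which leaves fewer UMIs, KO against WT gave 927 genes (immature, white pulp), 2103 (immature, red), 1533 (mature, white) and 287 (mature, red), and 2 lists in mature cDC1 of red pulp. Sums per lane, with fewer samples and 1 effect over both pulps, gave 2821 (immature) and 446 (mature). Clusters 13 and 7 alone, with fewer cells, gave 848 and 1014. No gene filter gave 44 and 41 (cDC2), 235 and 219 (pre-DC), 106 (B cells) and 249 (pulps differ, immature), and 10, 13 and 9 lists (immature red, mature white, pulps differ in mature). DESeq2 gave 22 in cDC2 of white pulp and 14 in B cells. The replicate block gave 6 (B cells), 564 (pulps differ, immature), 2262 and 2471 (pulps, WT and KO immature) and 12 lists in immature cDC1 of red pulp, and no block gave 26 (stages differ, red pulp). Isotype scaling gave 7 and 12 tags in immature and mature cDC1 of white pulp. With an estimated correlation 1 list passed in each KO against WT comparison of cDC1, 0 and 0 between pulps' effects, 3 and 7 between pulps in WT and KO immature cDC1, and 0 and 1 in mature. The mature share differed by -22.93 and -3.05 points with an unthinned Ccr7 UMI and by -1.237 in red pulp when clustered without called genes; the cycling share in red pulp by 0.605 with a thinned Mki67 or Top2a UMI.

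Signs turned for the IA_IE (0.046) and CD38 (0.023) tags in mature cDC1 of red pulp with isotype scaling and for C1qa in cDC2 of white pulp, at -3.53 (without KO replicate 1) to 2.60 (without WT replicate 3). The effect over both pulps from sums per lane had the other sign than 1 pulp alone for Gadd45b (-0.31, immature, white) and H2-Eb1 (0.10, mature, red). In mature cDC1 of white pulp signs turned in cluster 13 alone for Tapbp (0.035), Hmgcs1 (0.14), Cxcl9 (-0.15), Rab7b (-0.11), Wdfy4 (-0.48) and Havcr2 (-0.34), and in cluster 7 alone for Tapbp (0.063), Wdfy4 (-0.77) and Pfkp (-0.068).

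With 1 replicate left out, named here by genotype and number, KO against WT gave 1133 (KO 1) to 1509 (WT 2) genes in immature cDC1 of white pulp and 2240 (KO 2) to 2921 (WT 1) of red pulp. Mature cDC1 gave 2008 (WT 1) to 2556 (WT 2) and 329 (KO 2) to 449 (WT 2), with 4 (KO 3) to 23 (WT 2) and 9 (WT 3) to 23 (WT 2) in cDC2, 67 (KO 1) to 173 (WT 2) and 42 (KO 3) to 156 (WT 2) in pre-DC, and 0 (WT 1) to 12 (KO 2) in B cells. Effects differed between pulps for 24 (KO 1) to 78 (WT 1) and 119 (KO 1) to 249 (WT 2) genes in immature and mature cDC1. Between stages they did for 1202 (WT 3) to 1681 (WT 2) and 58 (WT 1) to 84 (KO 3). Pulps differed in 595 (WT 3) to 1056 (WT 1), 535 (KO 1) to 788 (KO 2), 2769 (WT 1) to 3248 (WT 2) and 1122 (KO 2) to 1413 (KO 3) genes in WT and KO immature and WT and KO mature cDC1. Tags called were 3 (KO 1) to 26 (WT 1), 5 (KO 1) to 47 (WT 1), 19 (KO 1) to 27 (WT 1) and 9 (KO 1) to 17 (WT 2). Lists called were 4 (KO 3) to 6 (WT 1), 5 (KO 1) to 11 (WT 3), 6 (KO 3) to 10 (WT 2) and 2 (WT 1) to 4 (WT 3). Lists between pulps' effects were 5 (WT 3) to 9 (KO 2) and 5 (WT 1) to 7 (WT 2). Lists between pulps were 12 (WT 1) to 14 (WT 3), 13 (KO 3) to 15 (KO 2), 8 (WT 1) to 10 (WT 2) and 6 (KO 1) to 9 (KO 3). The mature share differed by -20.13 (WT 2) to -16.88 (WT 3) and -2.465 (WT 3) to -1.78 (WT 2) points. The cycling share differed by -0.4277 (WT 2) to 2.989 (WT 1) and -1.7 (KO 3) to -0.2027 (KO 2). Alternatives for B cells of red pulp were not run, as the comparison had too few cells.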

Other observations

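The tests of explanations below, and the splits, were chosen only after the results were seen, as were the T and NK cell comparisons.

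Outside the dendritic lineage the counts were small and depended on the setting. In T cells 7 genes passed in white pulp and 1 in red pulp, and in NK cells 9 and 22. Red pulp sums of T and NK cells in KO were shallow, from 37322 and 69955 UMIs, so few calls there exclude little. In T cells of white pulp 80 genes passed with the replicate block, 99 with no gene filter and 1 to 26 with 1 replicate left out. In NK cells 39 and 66 passed with no gene filter, DESeq2 gave 48 in red pulp, and 1 replicate left out gave 6 to 23 in white and 6 to 51 in red pulp. Of 23 lists 10 passed in T cells of white pulp, 1 of them with an estimated correlation, the PERK-ATF4-CHOP list (adjusted p = 0.043, with 0 of 16 genes called). Eif4ebp1 rose in T cells of white pulp by 1.29, and the antibody transcripts Igha and Igkc were at -6.67 and -4.23. Their WT means there were 348 and 877 CPM, with larger SDs of 556 and 1370 (n = 3), so the size of these falls is uncertain. In immature cDC1 and pre-DC of white pulp Igha was at -3.15 and -3.66 and Igkc at -0.85 and -0.72. In NK cells of white pulp Cox6a2 rose by 3.01, Plcb4 by 2.22 and Atf3, a stress-induced transcription factor, by 1.80. In red pulp the NK proliferation gene Mki67 was at 3.67, and Gzmb, which codes for a killing enzyme, at -1.15. Transcripts named across classes also moved with the lane: Gm42418 was at -1.02 in immature cDC1, -1.18 in pre-DC, -1.01 in cDC2 and -1.15 in T cells of red pulp.

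PERK-ATF4-CHOP genes were higher in KO cDC1. Handling stress of the KO lanes as a whole would raise the list in other cells too, and its highest median over cDC2, pre-DC, B, T and NK cells was 0.237, in T cells of white pulp. The list passed there with 0 of 16 genes called, and Atf3 rose in NK cells of white pulp. Hspa5, not on this list, rose in NK cells (0.90, adjusted p = 0.0077) and pre-DC (0.27, adjusted p = 0.045) of red pulp. Its other edgeR values outside cDC1, from -0.44 to 0.54, did not pass. A weaker stress of all cells of the KO lanes stays open. With cells thinned to 1 depth the lowest list median of the 4 cDC1 comparisons was 1.45, which argues against depth. Without cluster 8, made up mostly of KO cells, the lower list median in immature cDC1 was 1.68. A stress of handling that touches only cDC1 cannot be separated from genotype, since each genotype and pulp was 1 lane, and a biological effect of the deletion may account for the pattern and stays a hypothesis.

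The mature share of cDC1 was lower in KO. Clustering without the genes called between genotypes left differences of -17.2 points in white and -1.24 in red pulp, which argues against clusters drawn by genotype as the whole cause. At 1 depth, cDC1 with a Ccr7 UMI differed by -19.5 and -2.50 points, more than free RNA gave in pre-DC, and without the cells that Scrublet called the differences were -18.3 and -2.01 points. A smaller yield of mature cells from the KO lanes was not tested and may contribute.

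Cox6a2 was higher in KO in cDC1, pre-DC, cDC2 and NK cells. The other markers of plasmacytoid dendritic cells had a median of 0.0371 in immature cDC1, which argues against such cells among the KO cells, and Cox6a2 per KO cell differed between classes by at least 34.2-fold, which argues against free RNA of 1 source. Extra copies of the region around Itgax with Itgax intact would raise Itgax, whose median over the classes was -0.0062, which argues against them. Copies in which Itgax is altered stay open, since Itgam and Itgad lay 0.757 above the other neighbours tested on the log2 scale (medians 0.722 and -0.0351, with 4 of 10 and 2 of 73 values called up), while Itgam was at -0.12 and 0.14 in NK cells. The labels do not say whether the KO animals carry a transgene there.

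Other splits of 3 against 3 samples are too few, at 10, for a share under 0.05. They also mix the 2 groups compared, which shrinks any difference and widens the spread, so low counts in them decide nothing. For KO against WT genes 1 split, the real one, gave as many in immature cDC1 (1635 in white and 3299 in red pulp; highest other 0 and 1), mature cDC1 (2582 and 515; 0 and 1), cDC2 (13 and 16; 2 and 1), pre-DC (127 and 116; 1 and 1), T cells of white pulp (7; 3) and NK cells (9 and 22; 2 and 1). In T cells of red pulp 5 splits gave as many as the real count of 1 (highest other 4), and in B cells of white pulp all 10 did, the real count being 0 (highest other 11). For surface tags (13, 29, 27 and 18) the count was 1 and the highest other 0, and for white against red pulp (1335, 1248, 3590 and 1823) it was 1, with a highest other of 1 in WT immature cDC1 and 0 in the others. For the gene lists 5 splits, the real one included, gave as many in immature cDC1 of white pulp (5 lists, highest other 6). In red pulp 5 did (6 lists, highest other 10), and in mature cDC1 2 and 3 did (8 and 4 lists, highest other 8 and 7). Other splits thus gave as many lists, so chance was not excluded for the number of lists called.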
